A study of Mus musculus with 2 samples.

How the data were processed

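Total RNA from blood of mice was hybridised to 2 Agilent mouse arrays, 1 for a heated sample and 1 for a control sample. Per the labels' protocols, RNA was prepared with a blood kit that lyses red and white cells differentially, globin transcripts were depleted, and 0.5 µg was amplified and labelled with Cy3. Per the file headers, images were read with Agilent Feature Extraction 10.7.1.1 under protocol GE1_107_Sep09, and the probes have mm9 coordinates; the submitters' processing notes name Agilent Feature Extraction 9.1. The deposited scanner files hold, per the file headers, linear intensity values of the green channel, namely a processed signal corrected by the scanner software, a mean signal and a local background. The deposited flags for other spot properties (saturation, outlier status and signal well above background) come from the same software, per the file headers. The authors' deposited values are log2 values; set against each array, they matched quantile-normalized log2 processed signals with r of 0.9999 on each array, the direction of the scanner files and a median of 5.26 in each column, and nothing about their scale or direction stayed open.

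Each array held 62976 spots, of which 59305 were outside the controls, for 56605 probes, with 300 probes at 10 spots and the others at 1. Outlier spots (168 on the heat array, 149 on the control array) were left out, no spot was saturated, and spots of one probe were averaged after log2. A probe counted as well above background when over 0.5 of its spots carried that flag. The main values are log2 of the processed signal minus each array's 75th percentile, which was 604 and 621 before log2 (heat and control). A gene's difference is the mean over its probes well above background on both arrays, 28755 probes or 18685 genes, of which 12173 had 1 such probe. Probes were named through unversioned transcript records in a table of the GRCm38.p6 assembly, which held 32994 of the 35886 probes with such a record (91.9%), and otherwise by the name in the files. No coordinates came from it.

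A difference of at least 1 on the log2 scale (2-fold) was counted, with no p-value, since each group held 1 array. For a gene list, the median difference was set against 10000 random lists of the same size, drawn from 20 bins of mean level, as a description of these arrays. Lists with fewer than 3 measured genes got values only. A gene whose probes were all not well above background on 1 array got a lower bound for its fold. The gene lists, the thresholds, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, among genes with a symbol and without a saturated probe, the 15 highest and 15 lowest differences with the same sign at every usable probe and under normexp and quantile normalization. It adds the 5 largest bounds in each direction, up to 4 measured members of each list with the largest differences, and 14 preset genes of heat shock, globin and housekeeping. After values had been seen, histone genes were also matched by their names in the array files, and an older symbol was dropped where a list held the current one. The spread of single spots used to judge the alternatives was 0.107, the SD of position-matched spot differences around their probe's mean. The 5 lists of macrophage, further macrophage, lymphocyte, further lymphocyte and osteoclast genes were chosen after seeing the data.

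The steps were tested on simulated data built on the arrays' own probes, with 200 changed genes and a spot SD of 0.15, over 18687 genes. For the 2-fold comparison, 100% of the genes planted at a log2 difference of 1.5, 2 or 3 were recovered and 0 of 18467 unchanged genes were called. For the gene lists, a list of 20 genes raised by 0.4 lay at the 100th percentile, and 5.0% of 200 random lists of unchanged genes lay outside the middle 95%. The simulation held no probe-specific error. The alternatives were normexp background correction (offset 50) with quantile normalization or the 75th percentile, quantile normalization, the median of detected probes, cyclic loess, the authors' value table, no filter on dim probes, the brighter 50% of detected probes, the brightest probe per gene, exclusion of saturated spots, a 4-fold threshold, random lists not matched on level and signals of mean minus background. R 4.3.3, limma 3.58.1, data.table (version 1.17.8), Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.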

Results

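Gene expression in mouse blood was measured on 1-colour Agilent arrays, with 1 array for a heated sample and 1 array for a control sample. Per the labels, the heated sample had 1 h of pretreatment in a water bath at 37 °C and then 1 h at 38.5 °C, and the comparison asked which genes the heat affects. The labels did not say whether the animals or the drawn blood were heated. They gave no temperature or time for the control sample, so heat, pretreatment and handling cannot be told apart in the differences below. The labels' protocols mentioned 3 replicates per line, but each group held 1 array here, so no difference below has a replicate check and none has a p-value. The number of arrays limits the precision. Both arrays lay on the same slide and were scanned in the same run, so slide and scan did not separate the groups. Each array held 56605 probes outside the controls, of which 30471 were well above background in the heated sample and 29460 in the control sample. Differences are heat minus control on the log2 scale, and coordinates are mm9, the build the file headers give for the probes.

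On both arrays, the genes of monocytes and of dividing cells were detected throughout, and many genes of lymphocytes, red cells and platelets were not well above background. All 16 monocyte markers were detected on each array, among them Lyz2 (lysozyme), Csf1r (the receptor for macrophage colony-stimulating factor) and Adgre1 (the macrophage antigen F4/80). All 25 cell cycle genes were detected too, including Mki67 (a marker of dividing cells) and Top2a (a topoisomerase of chromosome segregation). Of 18 B cell markers, 5 were detected on each array, and Cd79a of the B cell receptor complex and Ms4a1 (CD20) were not. Of 23 T cell markers, 13 were detected on the heat array and 11 on the control array. Cd3e, Lck, Cd4, Cd28 and Il7r were among them on both. Cd3g and Cd8a, which encode a chain of the T cell receptor complex and of the CD8 coreceptor, were not detected. The T cell shares, 56.5% and 47.8%, lay near those of all probes outside the controls, 53.8% on the heat array and 52.0% on the control array. Of 18 NK and cytotoxic cell markers, 5 and 4 were detected, and Gzmb (granzyme B) was not.

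Of 27 erythroid and reticulocyte genes, 15 were detected on the heat array and 16 on the control array, and Alas2, the heme synthesis enzyme of red cell precursors, was not. Of 8 globin genes, 2 and 3 were detected, and Hbb-b1, which encodes adult beta globin, was not well above background on either array. The labels' protocols included lysis of red cells and removal of globin transcripts. Of 20 platelet and megakaryocyte genes, 11 were detected on each array, and Itga2b and Gp9, which encode platelet surface glycoproteins, were not. Among neutrophil effector genes, 11 of 14 were detected, including Csf3r (the receptor for granulocyte colony-stimulating factor) but not Cxcr2 (the receptor that draws neutrophils to chemokines). As a background, 120 of 1106 olfactory receptor genes, which are not thought to be expressed in blood, passed the detection flag on the heat array and 110 on the control array. On both arrays Eif2s3y, Ddx3y, Kdm5d and Uty of the Y chromosome were detected, and Xist, the transcript that silences an X chromosome in females, was not.

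**Figure D1:**
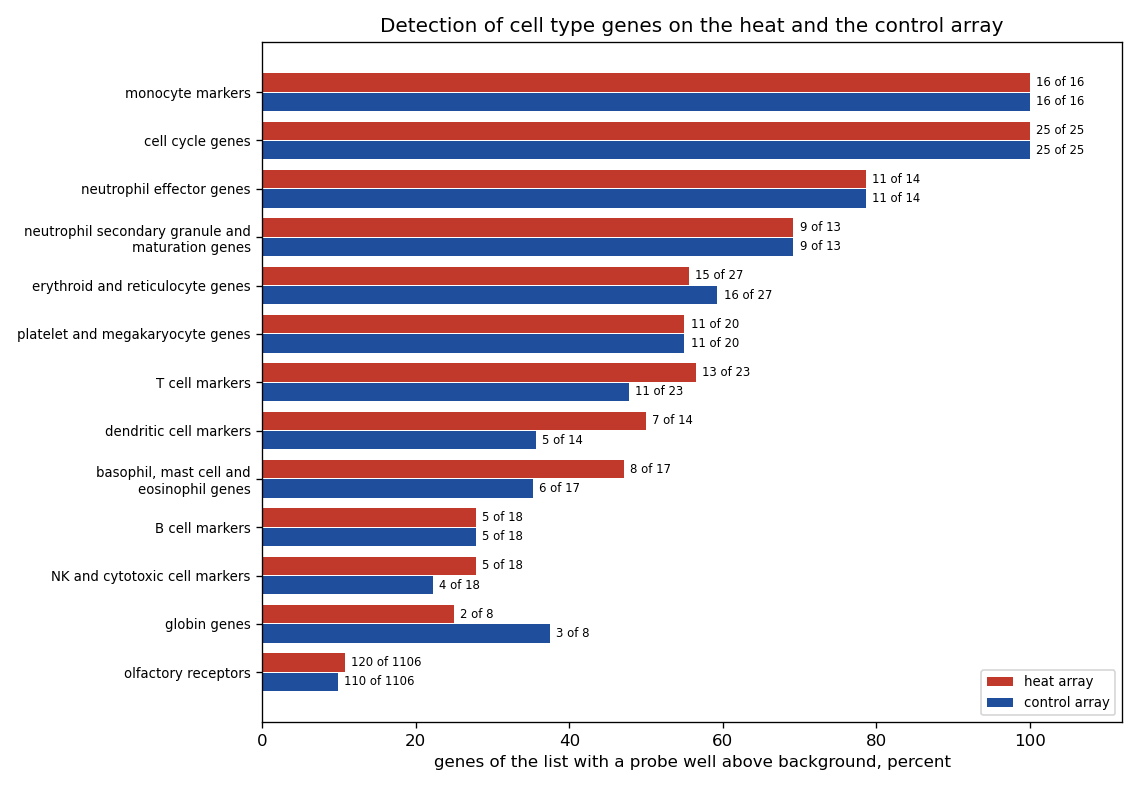
Share of the genes of each list that had at least 1 probe well above background (x axis, percent), with 1 bar for the heat array and 1 for the control array. All 16 monocyte markers and all 25 cell cycle genes were detected on both arrays, against 5 of 18 B cell markers and 120 or 110 of 1106 olfactory receptors.

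The arrays were closely alike, and the inducible heat shock genes stayed within 2-fold. Of 18685 genes with a probe well above background on both arrays, 39 were at least 2-fold higher in the heated sample and 84 at least 2-fold lower, which is 0.66% of them. Of these 123, 66 had no gene symbol, as had 6060 of the 18685. Alpl, which encodes tissue-nonspecific alkaline phosphatase, had the lowest difference among named genes at -4.09, and Pou2f3, a transcription factor of tuft cells, the highest at 2.88. Hspa1a and Hspa1b, which encode the inducible HSP70 chaperones, differed by 0.28 and 0.31. The differences of 95.6% of genes lay within 0.5 of 0, and Pearson's r between the arrays was 0.997 across 28755 probes, which are not independent replicates. Of the 123 genes apart, 120 rested on a single probe and 3 on several, namely Gm34786 at -1.21, Nhsl2 at 1.12 and Prrg4 at -1.09, which were looked up after the values were seen. Of these 3, only Gm34786 was 2-fold lower at each of its 3 probes. The count fell to 11 higher and 28 lower genes with normexp background correction and quantile normalization.

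Among the 15 named genes with the highest differences, Mroh5 was higher by 2.46, Flrt1 (a leucine-rich transmembrane protein) by 2.12 and Ghrl, which encodes the stomach hormone ghrelin, by 1.91. The olfactory receptor gene Olfr1500 was higher by 1.75, the zinc finger gene Zbed5 by 1.65 and Zscan5b by 1.58. Syt10, a synaptotagmin of vesicle release, was higher by 1.52, with a signal of 2216 against 794. Marco, a scavenger receptor of macrophages, was higher by 1.51, and Adarb1, an RNA-editing adenosine deaminase, by 1.45. Rtn4r, the Nogo receptor of neurons, was higher by 1.42, Rpl37 of the large ribosomal subunit by 1.36 and the keratin gene Krt6a by 1.22. Hs3st5, a heparan sulfate sulfotransferase, was higher by 1.20 and Cpeb1, which binds the polyadenylation element of mRNAs, by 1.17. With normexp and quantile normalization, the differences shrank to 1.64 for Pou2f3, 1.21 for Mroh5, 1.09 for Flrt1 and 1.16 for Ghrl, and 9 of the 15 lay under 2-fold, such as Olfr1500 at 0.83, Zbed5 at 0.81 and Rtn4r at 0.62, while Syt10 kept 1.47. Each of these genes rested on 1 usable probe, and that of Pou2f3 lies at chromosome 9, 42932963 to 42933022.

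Each of the 15 named genes with the lowest differences also rested on 1 usable probe. After Alpl, whose probe spans chromosome 4, 137309921 to 137311022, Xrcc6bp1 had -2.98 and Cldn12, a claudin of tight junctions, -2.10. Sprr2a2, which encodes a small proline-rich protein of the cornified envelope, had -2.06, with a signal of 24712 against 105757. Its probe also matches the near-identical Sprr2a1, so the value cannot be assigned to 1 of these genes, and it lies at chromosome 3, 92060587 to 92060646. Gtsf1, a gene of germ cells, had -1.99, the aldehyde dehydrogenase gene Aldh3a1 -1.90 and the alcohol dehydrogenase gene Adhfe1 -1.81. Rpl39l, which encodes a ribosomal protein paralogue, had -1.73 and Prf1, which encodes the pore-forming perforin of cytotoxic lymphocytes, -1.68. Ccdc73 had -1.67, the paired box gene Pax1 -1.58 and Raver1, which encodes an RNA-binding protein, -1.56. Serpinb6e (a serine protease inhibitor) had -1.52, the zinc finger gene Glis1 -1.44 and Angptl2, an angiopoietin-like secreted protein, -1.43. Raver1 had signals of 8564 and 26006 and Cldn12 of 528 and 2319 (heat and control), but the dimmer signal was 38.1 for Glis1, 30.0 for Xrcc6bp1, 32.0 for Mroh5, 32.8 for Pou2f3 and 37.3 for Flrt1, near the lowest that counted as well above background (24.9 on the heat array, 31.0 on the control array). With normexp and quantile normalization Alpl had -3.02, Xrcc6bp1 -1.60 and Cldn12 -1.98, and 4 of these 15 lay under 2-fold, such as Prf1 at -0.93 and Glis1 at -0.69.

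**Figure D2:**
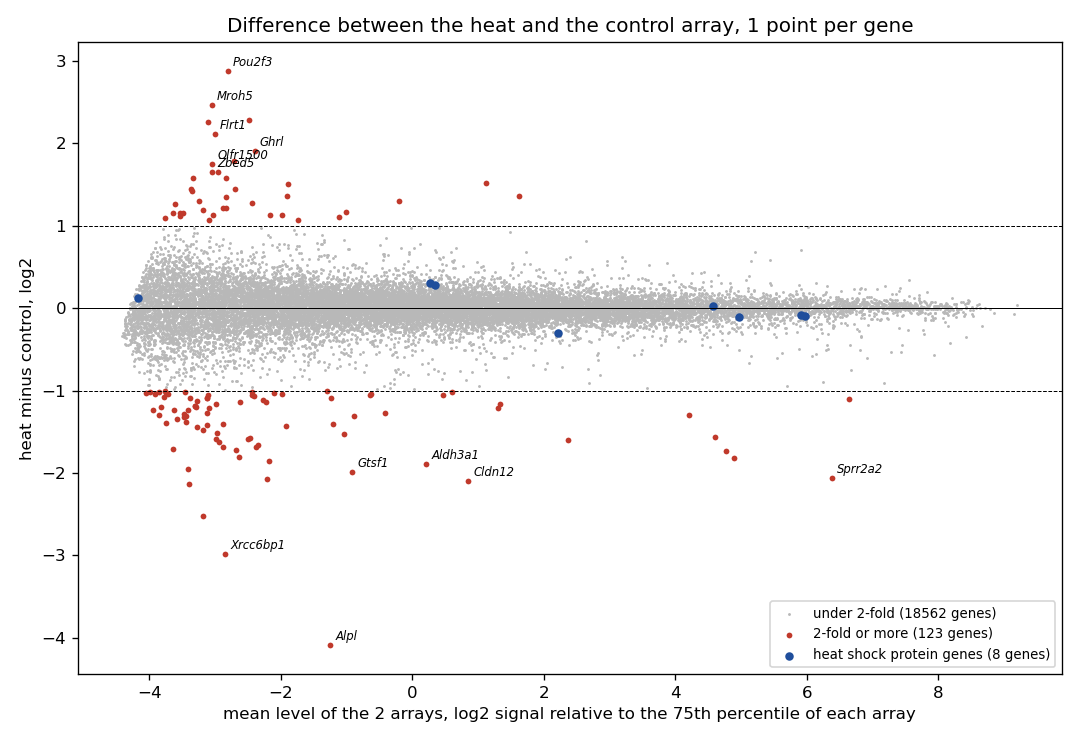
Heat minus control on the log2 scale (y axis) against the mean level of both arrays relative to each array's 75th percentile (x axis, log2), with 1 point per gene and dashed lines at 2-fold. The 123 genes at least 2-fold apart sit mostly at low levels, with a median level of -2.87 against -0.11 for all genes, and the 8 marked heat shock protein genes lie between the dashed lines.

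Inducible heat shock proteins and co-chaperones, which refold proteins after heat, were slightly lower in the heated sample as a list. Hspa1a and Hspa1b of the inducible HSP70 went the other way, at 0.28 and 0.31, the latter the highest value of the list. The list also holds constitutive members such as Hspa8. Of 28 genes, 25 were measured on both arrays, 6 of them higher and 19 lower, and none was 2-fold apart. The median was -0.08, at percentile 0.16 of 10000 random lists matched on level. Hspa13, an HSP70 relative of the endoplasmic reticulum, had -0.68, the small heat shock gene Cryab -0.44 and Cacybp -0.38, while Hspb1 differed by 0.12. Hsph1, which encodes HSP105, had -0.30, Hspd1 of the mitochondrial chaperonin -0.10, Hspa8 of the constitutive HSC70 -0.09 and Hsp90aa1 -0.08. Dnajb1, a partner of HSP70, differed by 0.03, and the sign of this value turned with normexp. Hspa1a lies at chromosome 17, 35106766 to 35106825, and Hspa1b at 35093374 to 35093405 for the parts their probes cover. Dnaja4 was well above background on the heat array only and has no measured difference, and Serpinh1 and Hspb8 were not on either array.

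Other stress lists lay inside the range of their random lists with the main scaling, and some of them outside with others. All 8 subunits of the TRiC/CCT chaperonin, which folds actin and tubulin, had values below 0, with Cct6a at -0.33, Cct3 at -0.20 and a median of -0.05 at percentile 9.70, although Cct2 changed sign under some scalings. The 4 heat shock transcription factors and partners had a median near 0 at percentile 48.4, with Hsf1, the main regulator of the response, at 0.01 and Hsf4 at 0.14. Of the 3 cold-inducible RNA-binding proteins, Cirbp was higher by 0.62 and at each of its 3 probes, Rbm3 by 0.09, and the list's median lay at percentile 85.1. The unfolded protein response of the endoplasmic reticulum had 8 genes higher and 14 lower and a median of -0.05 at percentile 4.0, with Asns at -0.25, Pdia4 at -0.22 and Hyou1 at 0.22; it lay outside under both normexp settings. Proteasome subunits, 10 higher and 21 lower, had a median of -0.04 at percentile 2.55, with Psmc5 at -0.29. This list lay outside, at percentile 1.38 to 2.35, with quantile normalization, cyclic loess, the authors' values and the brighter 50% of detected probes. Antioxidant and metal response genes had a median of -0.02 at percentile 22.0, with Mt2, a metallothionein, at 0.44 and Txnrd1 at -0.21, and lay at percentile 1.85 with dim probes kept. Glucocorticoid-responsive genes lay at percentile 38.7 with a median of -0.01, Cebpd at 0.43 and Tsc22d3 at 0.25. p53 and apoptosis genes, 14 higher and 8 lower, lay at percentile 87.0 with a median of 0.04, Trp53 at -0.34 and Fas at 0.23. Immediate early genes were 12 higher and 12 lower, at percentile 40.1, with Dusp5 at -0.81, Fosl1 at -0.64 and Btg2 at 0.43, but outside under both normexp settings and, at percentile 1.17, among the brighter 50% of probes.

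Of the 36 fixed lists with at least 3 measured genes, 7 lay outside the middle 95% of their random lists, where lists of unrelated genes give about 5%. Genes of one list can vary together, which random lists do not reproduce, so this count is no test of an excess over chance. Besides the heat shock list, the 7 held 6 lists of immune cells, of dividing cells and of chromatin. Genes of MHC class II presentation were lower in 6 of 7 cases, with H2-Aa at -0.29, H2-Ab1 at -0.23 and Cd74, the invariant chain, at -0.20, and their median of -0.20 lay at percentile 0.09. Ciita, the activator of class II genes, was the exception at 0.64. All 6 measured basophil, mast cell and eosinophil genes were lower, with a median of -0.44 at percentile 0.06, Ccr3 (the eotaxin receptor of eosinophils) at -1.04, Gata2 at -0.84 and Siglecf at -0.40. Of the 17 genes of this list, 9 were detected on neither array, such as Mcpt8, Cpa3 and Epx, so these cells were not evident in either sample. Some measured genes were dim, with log2 signals on the heat array of 5.15 for Gata2 and 6.74 for Ccr3, against 13.35 for Il6ra. Prss34, a mast cell protease, and Prg2, the eosinophil major basic protein, were detected on the heat array only and have no measured difference. With dim probes kept, the last list lay at percentile 25.6. Neutrophil effector genes were higher in 9 of 11 cases, with a median of 0.21 at percentile 100, the formyl peptide receptor genes Fpr1 at 0.68 and Fpr2 at 0.36, and Clec4e at 0.25. That list lay inside the middle 95% with a median of 0.08 at percentile 96.6 under normexp and quantile normalization, 0.06 at percentile 97.3 with dim probes kept and 0.02 at percentile 61.4 among the brighter 50% of detected probes.

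Cell cycle genes were 6 higher and 19 lower, with a median of -0.06 at percentile 0.86, Ccne1 (cyclin E1) at -0.23 and Tyms (thymidylate synthase) at -0.16. DNA repair genes were 6 higher and 15 lower, with a median of -0.06 at percentile 1.76 and Xrcc5, which encodes a Ku subunit, at -0.37. Of 56 histone genes, 38 were higher, and the median of 0.06 lay at percentile 99.7, with H1f2, a linker histone gene, at 0.37 and the histone variant gene Macroh2a3 at -0.44. Each of these lists lay inside the middle 95% under several alternatives. The cell cycle list did so under both normexp settings (percentiles 3.21 and 4.47) and with random lists not matched on level (2.81). The DNA repair list did so with quantile normalization (3.33), the authors' values (3.09), dim probes kept (2.70), the brighter 50% of probes (3.08) and unmatched random lists (3.52). The histone list did so with cyclic loess (95.8) and the authors' values.

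The remaining immune lists lay inside the middle 95% with the main scaling, but not in every setting. Inflammatory cytokines and NF-kB targets had 13 genes higher and 12 lower and lay at percentile 49.5, with the neutrophil chemokine genes Cxcl2 at 0.69 and Cxcl1 at 0.59, the interferon-induced Cxcl10 at -0.46 and Tnf at 0.28. Interferon-stimulated genes, 11 higher and 20 lower, had a median of -0.04 at percentile 5.79, with Oasl2 at -0.40, Ifit3 at -0.31 and Stat2 at 0.29. Interferon-stimulated genes lay outside under 6 alternatives, namely both normexp settings, quantile normalization (percentile 1.25), cyclic loess (0.55), the authors' values (1.19) and the brighter 50% of probes (0.05). Monocyte markers had a median near 0 at percentile 40.1, with Fn1 (fibronectin) at -1.40, Lyz1 at -0.60 and Ccr2, the receptor for monocyte chemoattractant, at 0.73. Neutrophil secondary granule and maturation genes lay at percentile 59.4 with a median of 0.03, Camp at -0.37 and Mmp8 at 0.25. The 3 measured myeloid progenitor granule genes had a median of -0.13 at percentile 10.3, with Mpo (myeloperoxidase) at -0.38. Among the measured lymphocyte genes, the medians lay at percentile 55.6 for B cell markers (Cd79b 0.33) and percentile 49.0 for T cell markers (Cd8b1 -0.57, Cd28 0.35). NK and cytotoxic cell markers lay at percentile 45.8, and at percentile 98.9 with dim probes kept. Dendritic cell markers lay at percentile 84.5, with Batf3 at 0.22 and Siglech at -0.19, but 3 of them had a median of -0.19 at percentile 1.1 among the brighter 50% of probes.

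Erythroid and reticulocyte genes had a median of -0.03 at percentile 20.6, with the transferrin receptor gene Tfrc at -0.60, the carbonic anhydrase gene Car2 at -0.59 and Rhd at 0.41. The 2 measured globin genes, Hba-a1 and Hba-a2, which share a probe match, differed by 0.03 and less. Platelet and megakaryocyte genes lay at percentile 91.5 with a median of 0.12, F2rl2 at -0.66, Treml1 at 0.40 and Pf4 (platelet factor 4) at 0.26, and 4 of them lay at percentile 99.9 among the brighter 50% of probes. Markers of cells outside the blood lay at percentile 30.4 for liver, percentile 52.0 for muscle, percentile 52.8 for skin and percentile 76.7 for endothelium. Housekeeping genes had a median of -0.03 at percentile 8.43, with Rplp0 at -0.54, Actb (beta actin) at -0.21 and Gapdh at 0.03. Cytosolic ribosomal proteins lay at percentile 7.81, nuclear genes of oxidative phosphorylation at percentile 25.2, with Cox6a2 at -0.67, and mitochondrial ribosomal proteins at percentile 5.27, with Mrps14 at -0.79 from probes at -1.57 and -0.01, and at percentile 1.21 with dim probes kept. Olfactory receptors lay at percentile 76.0, and at 0.78 with dim probes kept.

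**Figure D3:**
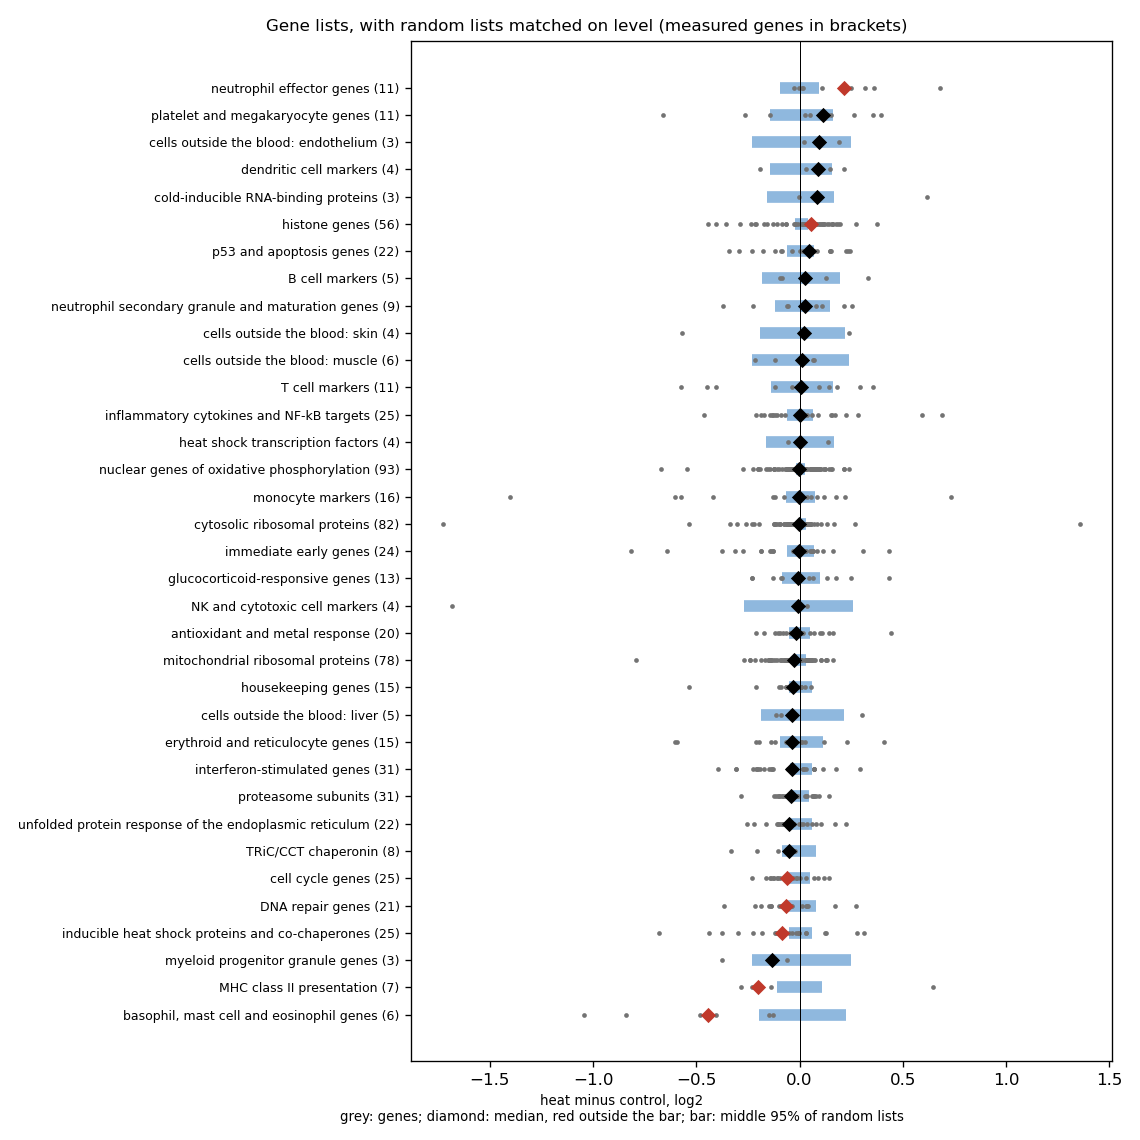
Heat minus control on the log2 scale (x axis) for each gene list with at least 3 measured genes, without the olfactory receptors. Grey points are genes, diamonds are medians and bars are the middle 95% of the medians of 10000 random lists, and the 7 red diamonds, such as MHC class II presentation at -0.20, lie outside their bars.

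Genes detected on 1 array only were 1147 for the heat array and 543 for the control array, and most had small bounds. The detection floor differed, as the lowest signal well above background was 24.9 on the heat array and 31.0 on the control array. Nkg7 passed on the heat array only, at a log2 signal of 4.98 against 5.02, so these counts alone do not show higher expression. A bound rests on 1 probe, the brightest of the gene on the array that detected it. It sets the brighter array against the higher of the dim probe's own value and the lowest signal that counted as well above background on the dim array. By this bound 119 genes of the heat array and 167 of the control array were at least 2-fold apart. In the heated sample, Cpa1, which encodes a pancreatic carboxypeptidase, was at least 9.80-fold higher, Cdh2 (N-cadherin) and Lrrtm4 at least 7.59-fold, Efcab5 at least 7.41-fold and Glyat, a glycine acyltransferase, at least 7.33-fold. In the control sample, Jph3 was at least 6.22-fold higher, the olfactory receptor gene Olfr5 at least 6.08-fold, Samd5 at least 5.58-fold and Slc6a20b at least 5.46-fold. Of the genes named here, Cpa1, Olfr5 and Samd5 have 1 probe on the array. The others have 2 to 4, and their further probes did not enter the bounds, so the folds hold for the probe used. These bounds depend on the background correction: on the log2 scale, normexp and quantile normalization lowered them from 3.29 to 1.98 for Cpa1, from 2.92 to 1.78 for Lrrtm4, from 2.64 to 1.49 for Jph3 and from 2.45 to 1.40 for Slc6a20b.

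Replicate spots gave the technical precision within an array. Across 282 probes with 10 spots each, the median SD between spots was 0.05 in the heated sample and 0.02 in the control sample on the log2 scale. The means of these probes differed between the arrays by -0.48 to 0.25, and 0 of them were 2-fold apart. The 8 detected E1A spike-in probes, which match added control transcripts and no mouse gene, differed by -0.12 to 0.16. The spots of the named genes with 1 probe had no such repeats.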

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

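The alternatives were chosen before the data were examined, except the counts over genes with several probes, which were chosen after seeing them. No paired analysis was possible because each group held 1 array. Of 123 genes at least 2-fold apart (39 higher, 84 lower), normexp with quantile normalization left 39 (11 higher, 28 lower) and normexp with the 75th percentile 37 (12 higher, 25 lower); normexp adds an offset that shrinks differences of dim probes. Without the filter on dim probes the count was 1748 (734 higher, 1014 lower), among the brighter 50% of detected probes 17 (3 higher, 14 lower), and at 4-fold 12 (5 higher, 7 lower). Over genes with several probes the count was 3 (1 higher, 2 lower) by their mean, and 1 (0 higher, 1 lower) where every probe was 2-fold apart. Under the other settings it was 123 to 132. The median spot SD was 0.0785 in the heated and 0.0504 in the control sample with mean minus background signals, against 0.0510 and 0.0235; the cause was not tested. Of the 7 lists outside their random lists, 4 to 7 stayed outside under the 9 alternatives that could move list percentiles, and up to 5 others joined them. Among the brighter 50% of probes only 28 lists had a percentile, and the basophil, mast cell and eosinophil list had none, so it could not be assessed there. The heat shock and MHC class II lists stayed outside in all 9. Mean minus background signals were run on spot SDs only. Of 176 named genes, 162 kept their sign under the 7 scalings, and the 14 others differed by at most 0.102. The signs of 30 had been a condition of their choice under normexp and quantile normalization. Of 32 named genes at least 2-fold apart, 14 fell under 2-fold with normexp and quantile normalization, 17 fell under 2-fold with normexp and the 75th percentile and 10 without the dim filter. The lower bounds of the 10 genes detected on 1 array shrank with both normexp settings. No spot was saturated, so leaving such spots out moved nothing, the median scale shifts every gene alike, and scaling does not alter detection flags.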

Other observations

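The tests of the other probes of a gene and of the B and T cell markers were chosen only after the results were seen, as were the added gene lists. The measure for the B and T cell markers was restated 2 times, from a gap in level to a test across genes and then to shares detected, and its last bounds were written after the shares had been seen. The first test of macrophage-type cells, on the levels of the first macrophage and lymphocyte lists, was replaced by detection in further lists not yet read.

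Where a gene has several probes, the differences that all of them share were mostly under 2-fold, unlike the large ones at single probes. Of 6512 such genes, 4 were higher by 0.5 or more at every probe and 10 lower. The higher ones were Il3ra, the interleukin 3 receptor alpha chain, at 0.92, Spryd3 at 0.73, the nuclear long non-coding RNA Neat1 at 0.68 and Tns1 (tensin 1) at 0.66. Among the lower ones were Gm34786 at -1.21, the largest, and Pde4c, a cAMP phosphodiesterase, at -0.95. Dcstamp, which is required for fusion of osteoclasts, had -0.72, and Oscar, an osteoclast receptor, -0.58. A list of 13 further osteoclast genes, 3 of which other lists also hold, had 8 genes lower, with Calcr at -0.64 and Ocstamp at -0.43, but its median of -0.03 lay at percentile 22.2 of random lists, so the list as a whole did not stand apart. A first version of 18 genes also held 5 whose values had been seen, and it did stand apart, but those 5 had been picked for their low values. Of the other added lists, macrophage genes had a median of 0.07 at percentile 99.6, further macrophage genes 0.07 at percentile 96.9, lymphocyte genes 0.34 at percentile 99.9 and further lymphocyte genes -0.14 at percentile 4.74, with 7 and 3 lymphocyte genes measured.

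Most genes with a probe 2-fold apart and other probes may not reflect a difference of the whole transcript. For 75 genes with a probe at least 2-fold apart and other usable probes, the median difference of those others, in the direction of the probe apart, was 0.005 (bootstrap 95% interval -0.05 to 0.07), against 1.25 at the probe apart; 6 genes reached 0.5. This argues against a whole-transcript difference for these genes as a set, and leaves isoforms and spot defects open. Noise of single spots could not be decided: 2 of 2820 position-matched spots of replicated probes were 2-fold apart, 0.071% (exact 95% interval 0.009% to 0.256%), against 0.314% of probes with 1 spot at matched levels. That interval treats the spots as independent, although they come from 282 probes, so it may be too narrow for a share across probes. For the 120 genes without a second usable probe, noise and an effect of the heat cannot be told apart with 1 array per group.

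Fewer lymphocyte than monocyte genes were detected on both arrays: 43.9% of B and T cell markers on the heat array (18 of 41) and 39.0% on the control array (16 of 41), against 16 of 16 monocyte markers. Of all probes outside the controls, 53.8% and 52.0% were well above background, and the gap to the B and T cell markers came mainly from the B cell markers, 27.8% of which were detected on each array. These shares are the pattern itself, so they exclude no cause, and an effect of red cell lysis and globin removal stays open. A technical hypothesis is RNA of dividing macrophage-type cells in place of mixed blood leukocytes, which includes a mix-up of samples. In lists written before their values were read, 100% of 15 macrophage genes and 26.7% of 15 lymphocyte genes were detected on each array, Cybb and Tlr2 among the former. Earlier lists gave 20 of 20 macrophage genes, of which blood myeloid cells also express 12, and 8 and 7 of 20 lymphocyte genes; the other 8 macrophage genes, such as Trem2, Lpl and Mmp12, were all detected on both arrays, as were all 25 cell cycle genes, which goes against resting blood monocytes alone, though no reference profile was tested; no biological explanation was tested, since the design gives none.

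The arrays were so alike that they might hold 1 RNA. With 1 labelled cRNA on both, differences at 2 probes of one gene should be unrelated, provided that probes of one gene share no technical error. Across 6512 genes, which are not independent replicates, Pearson's r was 0.280 (bootstrap 95% interval 0.245 to 0.316) and Spearman's rho 0.338 after removal of the trend with level. This argues against 1 labelled cRNA only under that condition, which was not tested. Labelling of 1 RNA in separate reactions and 2 closely similar RNAs cannot be told apart: 0 of these genes with 2 or more probes differed 4-fold at every probe in one direction, and each group held 1 array.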
